A study of Mus musculus with 12 samples.

How the data were processed

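The series measured N6-methyladenosine (m6A) on RNA of BV2 cells, an immortalised mouse microglial line, treated with bacterial lipopolysaccharide (LPS). The labels describe 12 libraries in 4 groups, with 3 replicates per group: an m6A antibody pull-down (IP) and an input fraction from wild-type (WT) cells and from cells with Mettl3 knocked out (KO). Per the labels' protocols, polyadenylated RNA was selected, fragmented and precipitated with an m6A antibody, and strand-marked libraries were made from the IP and the input. The same protocol text speaks of neuroblastoma cells, while the sample labels name BV2 microglial cells. The submitters' processing notes name fastp, FastQC, HISAT2, HOMER, StringTie and edgeR with no versions or roles. The peak caller, its settings, the genome build and whether replicates were pooled before peak calling are not given in the sources used here.

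The values used here are 2 deposited peak lists, 1 per genotype. Per the file headers, the authors gave each peak a log2 fold of IP over input, a p-value, an adjusted p-value, an annotated region and a gene. The log2 values and the p-values are the authors' own, and no per-library value entered any comparison. All deposited p-values lay below 0.05; 106 WT peaks and 122 KO peaks had an adjusted p above 0.05. Depth per library is therefore unknown here, and the intervals given cover counting of peaks or genes only. Start positions in the lists were counted from 0, since 5098 WT peaks and 5186 KO peaks began exactly at the annotated start of their gene once 1 was added, so 1-based positions are printed. A peak's span is a stretch of genome that includes introns: 40.1% of WT peaks and 38.9% of KO peaks spanned more than 1000 bases, up to 2722199 bases. Of 13054 genes whose symbol is in the RefSeq table of assembly GRCm38.p6, 13053 overlapped their position there; the lists name no build, so the positions are given as deposited.

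Overlap was counted with bedtools 2.31.1 as at least 1 shared base on the same strand, with 95% Wilson intervals. A gene's value is the log2 of its strongest peak in a list. Differences are KO minus WT, so a negative difference is a lower deposited value in the KO list. Each list carries its own IP efficiency and scaling, so side-by-side values describe these lists and are no test of the genotypes. A set of 20 gene groups were fixed before the data were examined. Their share of genes with a peak in 1 list only was compared with all 14078 genes with a peak by two-sided Fisher's exact tests, 40 in all, with Benjamini-Hochberg adjustment. These tests compare the 2 lists, not the conditions. The median difference of each group with at least 2 genes in both lists was placed among 10000 random gene lists of the same size, matched on the mean of the WT and KO values in 20 bins and drawn with replacement. A further match used 10 bins of mean value and 3 of gene span. KEGG pathways named in the deposited lists were treated in the same way where at least 30 genes had a peak in both lists, a step chosen after seeing the data, as were the gene-level differences between the lists and the matched random lists themselves.

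Genes are named by a rule fixed before the data were examined: Mettl3 and the other m6A writers, erasers and readers with a peak; Batf; for each group the 4 members with the strongest peak and up to 4 members per genotype with a peak in that genotype only; and the 10 genes with the strongest peak in each list, and among the genotype-specific genes of each. Some genes that the rule takes are not reported here. Other named genes were chosen after their values were seen. The alternatives tried were stricter thresholds (adjusted p of at most 0.001, or fold of at least 4), a reciprocal overlap of 50%, strand ignored, equal numbers of peaks, merged peaks, short peaks, peaks inside the annotated gene, the mean over a gene's peaks, and differences centred on the median of all genes. They were run for every gene that the rule names with a peak in both lists and for the other genes named. Input expression, differential m6A between genotypes, the joint analysis of both, the sequence motif and positions by peak midpoint were not analysed here, because they need per-library values or a genome sequence. Computations used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9. The steps were tested on simulated data made from the WT list. All 999 genes that lost every peak were recovered, and none of 36267 peaks overlapping no other WT peak was wrongly called shared or unshared. The simulated list kept the exact coordinates of the remaining WT peaks. This therefore checks the code and not the matching of partly overlapping peaks. Of 100 simulated groups of 20 genes shifted by -0.3, 100 fell below the central 95% of random lists, and 4.5% of 200 unshifted groups fell outside the central 95%. These groups were random genes, so groups that share gene length, expression or peak width were not simulated. The simulated noise had a fixed size that was not taken from the spread between the 2 real lists. All shifted groups were drawn from 1 set of shifted genes. The share detected therefore checks the code and does not give the sensitivity in the real lists.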

Results

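Methylated RNA immunoprecipitation and sequencing was used to map m6A, the methyl mark that the METTL3 enzyme complex places on adenosines of messenger RNA, in LPS-treated BV2 microglial cells with and without Mettl3. The 12 libraries comprised 3 IP and 3 input libraries per genotype, and the series text sets out to find regulators through which METTL3 acts on the microglial response. The values below come from 1 peak list per genotype, so there were no replicate values from which to measure spread. Every enrichment given is the authors' deposited log2 of IP over input for a peak, and every adjusted p beside a peak is theirs.

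The first question was how many m6A peaks each genotype carried and how strong they were. The KO list held more peaks than the WT list, 41153 against 36682, on slightly fewer genes, 13031 against 13370. Strong peaks went the other way. At 4-fold enrichment or more there were 4307 WT peaks and 1618 KO peaks, and at 16-fold or more 248 and 62, so the ratio of KO to WT peaks went from 1.12 over all peaks to 0.376 at 4-fold. The median log2 enrichment was 0.83 in WT (interquartile range 0.62 to 1.30, 95% interval of the median 0.83 to 0.84) and 0.70 in KO (0.52 to 0.99, 95% interval 0.70 to 0.71). Genes with a peak carried on average 2.74 peaks in the WT list and 3.15 in the KO list.

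**Figure D1:**
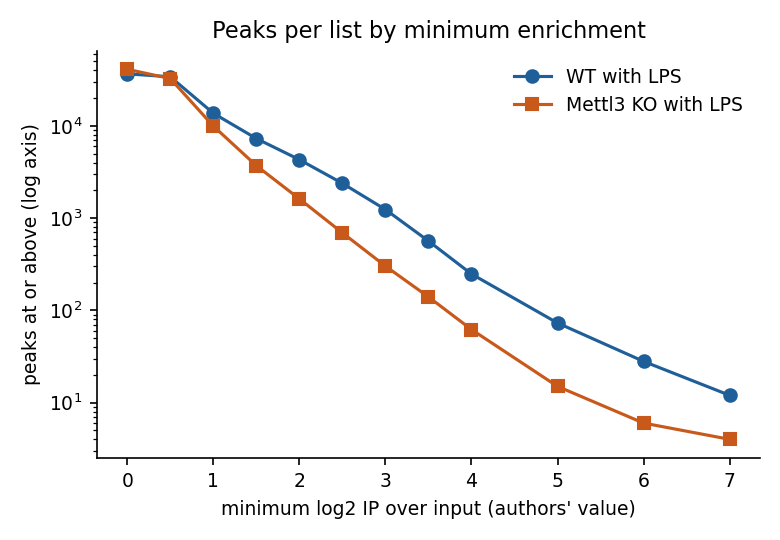
Number of peaks (log axis) at or above each minimum log2 enrichment of IP over input in the WT list (circles) and the Mettl3 KO list (squares). The KO list is larger with no minimum, 41153 against 36682, and smaller from 0.5 upwards, with 1618 against 4307 peaks at a log2 of 2.

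Most positions were marked in both lists. Of the WT peaks, 77.2% (95% interval 76.7 to 77.6) overlapped a KO peak, and of the KO peaks 72.9% (72.5 to 73.3) overlapped a WT peak. Peaks without a partner were weaker in both lists, with a median log2 of 0.74 for 8381 WT peaks and 0.56 for 11152 KO peaks. Among strong peaks, however, the WT list had the larger unmatched share: 16.3% (15.2 to 17.4) of WT peaks at 4-fold or more had no KO partner at any strength, against 8.47% (7.21 to 9.92) of such KO peaks without a WT partner. The overlap required decided these shares to a large extent: with 50% of both peaks overlapping, 53.1% of WT peaks and 47.3% of KO peaks were shared.

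A narrower comparison used the 2916 peaks with identical coordinates and strand in both lists, chosen after seeing the data. One is the main Mettl3 peak, and another covers Junb, an AP-1 transcription factor, with a log2 of 2.03 in WT and 1.12 in KO. Of these pairs, 61.9% (60.1 to 63.6) had the lower value in KO, and the difference was larger among pairs with a mean log2 above 1. The median difference was -0.029 (95% interval -0.039 to -0.021) for pairs with a mean log2 below 0.75, -0.015 (-0.035 to 0.0021, an interval that includes 0) between 0.75 and 1, -0.36 (-0.44 to -0.27) between 1.5 and 2, and -0.83 (-1.07 to -0.62) from 3 upwards.

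**Figure D2:**
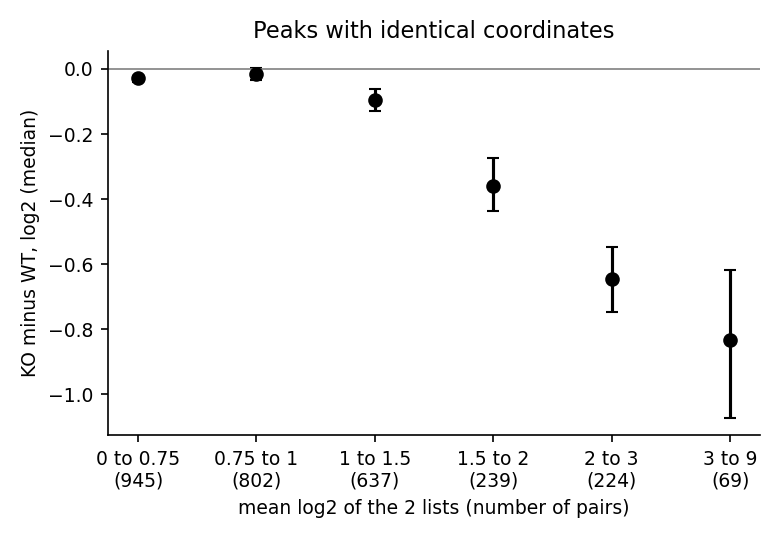
Median KO-minus-WT difference in log2 enrichment for peaks with identical coordinates, by the mean log2 of both lists, with the number of pairs under each bin and 95% order-statistic intervals as bars. The median lies at -0.029 in the weakest bin and at -0.83 in the strongest.

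The series text places m6A mainly in coding sequence, in 3' untranslated regions (UTRs) and near stop codons. In the deposited annotation, 3' UTRs held 53.0% (52.5 to 53.5) of WT peaks and 51.4% (50.9 to 51.9) of KO peaks, the largest class in both lists. Coding exons followed with 21.1% (20.6 to 21.5) in WT and 25.1% (24.7 to 25.5) in KO, and 5' UTRs held 11.9% in each list. Exons of noncoding RNAs held 8.15% (7.87 to 8.43) of WT peaks and 6.41% (6.18 to 6.65) of KO peaks, and had the highest median log2 of the 5 main classes, 1.26 and 0.96. At 4-fold or more the coding-exon share was 9.54% in WT (411 of 4307 peaks) and much the same in KO (162 of 1618), and noncoding exons held 18.0% and 20.3%. The annotation has no stop-codon class.

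Mettl3 itself carried 3 peaks in the WT list and 6 in the KO list. Its strongest peak lay at the same place in both, on chromosome 14 from 52301301 to 52303977 on the minus strand, annotated as 3' UTR, with a log2 of 1.57 in WT (adjusted p = 1.29e-127) and 2.07 in KO (1.89e-124). This value measures enrichment of the fragment in the IP and not the amount of Mettl3 RNA, so it checks neither the knockout nor the labels. All 13 listed m6A writers and cofactors had peaks in both lists, and for 8 the strongest value was lower in KO. Those 8 included the adaptors Rbm15 (3.10 in WT, 2.05 in KO) and Rbm15b (3.38 and 2.68), the METTL3 partner Wtap (2.21 and 1.40), Virma (1.79 and 1.19) and Zc3h13 (2.03 and 1.63). Cbll1 stood at 2.14 and 1.32, with the opposite order among peaks of at most 1000 bases. Zcchc4, a ribosomal RNA methyltransferase, stood at 1.63 and 1.35, with the opposite order among short peaks, and the cap methyltransferase Pcif1 at 1.51 and 0.93. Higher KO values were listed for Mettl3, for its catalytic partner Mettl14 (0.82 and 1.01) and for Mettl16, a separate m6A methyltransferase (1.11 and 1.79). Mettl5 (1.42 and 1.44) and its cofactor Trmt112 (0.93 and 1.07) were also slightly higher in KO. The order of Mettl3 and of Mettl5 turned both among peaks of at most 1000 bases and with the mean over a gene's peaks, and that of Mettl14 and Trmt112 with the mean.

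Among the readers, 14 of 15 listed genes had peaks in both lists, and 12 had the lower value in KO. Of the 5 YTH-domain proteins, which bind m6A directly, 4 were among them: Ythdc1 at 2.73 in WT and 1.48 in KO, Ythdf2 at 2.58 and 1.49, Ythdf3 at 2.97 and 2.16, and Ythdf1 at 1.56 and 1.04. Ythdf1 and Ythdf3 had slightly higher KO values among peaks of at most 1000 bases. Igf2bp3 stood at 1.50 and 0.70, Prrc2a at 1.78 and 1.47, Eif3a at 1.54 and 1.19, Hnrnpa2b1 at 1.59 and 1.50, and Igf2bp2 at 0.89 and 0.64; the last 4 had the opposite order among short peaks. Rbmx (1.36 and 1.19) turned with the mean over peaks, and Elavl1 (2.07-fold and 1.61-fold) and Fmr1 (0.76 and 0.64) were lower in KO. Hnrnpc (0.64 and 0.73) and Ythdc2 (0.81 and 0.89) were the 2 readers with the higher KO value. The demethylase Fto stood at 1.74 and 0.96, an order that also turned among short peaks, and the other eraser, Alkbh5, at 0.70 and 0.68. The median differences of writers (-0.39) and readers (-0.34) lay at the 72.8th and 27.6th percentile of matched random lists. With peaks of at most 1000 bases both medians turned, to 0.026 for writers (80.0th percentile) and 0.039 for readers (85.8th). With the mean over peaks they were -0.34 (7.52nd percentile) and -0.18 (18.2nd), and for writers -0.58 (22.6th) at an adjusted p of at most 0.001.

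The transcription factor gene Batf, which the series text singles out, had 2 peaks in the WT list and none in the KO list. The stronger one, annotated as 3' UTR, spanned chromosome 12 from 85689763 to 85709081 on the plus strand with a log2 of 2.92, or 7.56-fold, and an adjusted p of 7.34e-40. The other, annotated as 5' UTR, spanned 85686694 to 85689537 with a log2 of 1.88. Together they covered most of the gene, which the list places from 85686669 to 85709087. Both peaks are too long to enter the short-peak comparison used below, so that setting leaves Batf with no peak in either list. Input expression was not analysed, so the missing KO peak does not separate less m6A from less Batf RNA. Batf was 1 of 1047 genes with a peak in the WT list only and ranked 194 among them by its strongest peak. A KO-only peak was found in 708 genes. At 4-fold or more, 387 genes had a WT peak and no KO peak of any strength, and 75 the reverse.

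**Figure D3:**
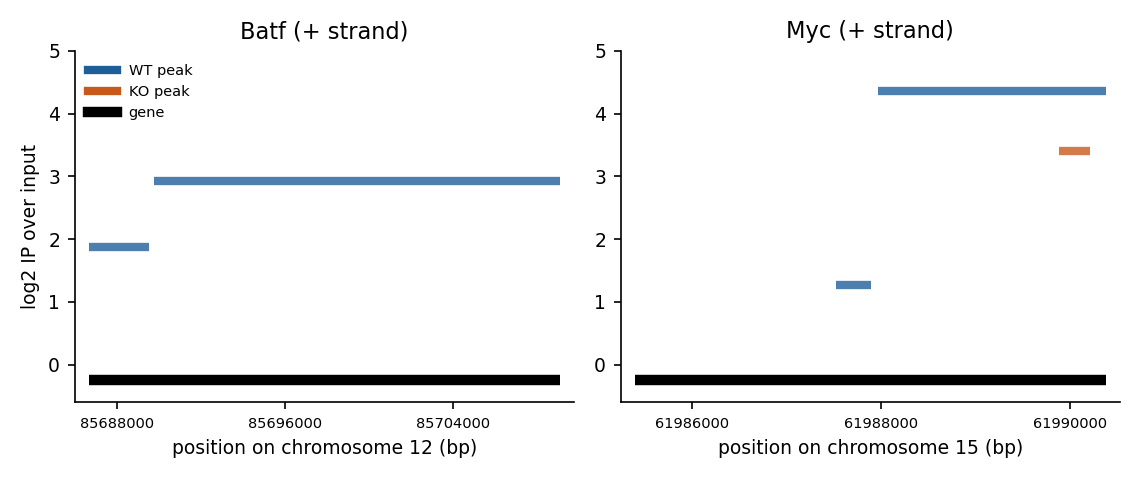
Peaks of Batf and Myc drawn to scale along the gene (black bar, placed below 0 for display), with genomic position in bases on the x axis and the log2 enrichment of IP over input on the y axis. Batf has WT peaks at 1.88 and 2.92 and no KO peak, and Myc has WT peaks at 1.27 and 4.36 and a shorter KO peak at 3.40.

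Genes of the LPS response were found on both sides of this split. The cytokine genes Csf2 (log2 of 1.46), Csf3 (1.20), Il6 (0.99) and Il1a (0.55) had peaks in WT only, as did Socs1 (0.91), a brake on cytokine signalling, and Gbp3 (0.85), an interferon-induced GTPase, and the long noncoding RNAs Ptgs2os (0.85) and Gas5 (0.65). The chemokine gene Ccl4 (0.55), Arg1 (0.93), Hmox1 (0.45) and the microRNA host Mir155hg (0.55) had peaks in KO only. Several of these values were low, as the lower quartile of all peaks was 0.62 in WT and 0.52 in KO. A small difference near the calling threshold could place such a gene in 1 list only. As for Batf, a difference in m6A is not separated from one in RNA amount. None of the 20 gene groups was over- or under-represented among WT-only or KO-only genes by Fisher's exact test (smallest adjusted p = 1.0 over 40 tests, with 0 tests below 0.05 before adjustment). With both lists limited to 4-fold peaks, ribosomal protein genes were over-represented among KO-only genes, with 3 against 0.220 expected (adjusted p = 0.0253). Among them were Rps23 and Rps19, whose KO values lay just above 4-fold.

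For the 12323 genes with a peak in both lists, strongest-peak values were compared side by side. The KO value was lower for 9049 genes and higher for 3274, with a median difference of -0.25 (interquartile range -0.64 to 0.015). It was lower by 1 or more for 1175 genes and higher by 1 or more for 88. Much of this rested on peaks spanning more than 1000 bases: among shorter peaks the median difference was -0.054, 412 genes were lower and 148 higher by 1 or more, and 1788 of 9360 genes (19.1%) changed order. With the mean over a gene's peaks, 1796 of 12323 genes (14.6%) did. Below, short peaks are those of at most 1000 bases, and group medians are read against the -0.25 of all genes.

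The AP-1 and BATF group of transcription factors held some of the strongest peaks; it also takes in Irf4 and Irf8, interferon regulatory factors that bind DNA together with BATF and are not members of that family. Of its 17 genes with a peak in both lists, 15 had the lower value in KO: Fosb stood at 5.32 in WT and 3.79 in KO, Jun at 4.61 and 3.65, and Jdp2 at 3.83 and 2.72. Maf was higher in KO, at 3.25 and 3.63. The group's median difference of -0.76 lay at the 18.2nd percentile of random lists of equally strong genes, was -0.037 (54.8th) over the 8 genes with short peaks in both lists, and -0.38 (50.2nd) with the mean over peaks. The chromatin and transcription regulators were similar, with 18 of 20 lower in KO and a median of -0.66 at the 58.0th percentile, of -0.074 (48.8th) with short peaks and of -0.21 (36.4th) with the mean over peaks. Tet3, a DNA demethylation enzyme, stood at 3.99 and 3.07, Nsd1 at 3.68 and 3.18, and the acetyltransferase Ep300 at 3.08 and 2.19. Chd4 was higher in KO, at 3.65 and 3.99, an order that turned with the mean over peaks. Myc, in the cell cycle group, stood at 4.36 and 3.40, but its KO peak spanned 325 bases against 2409 in WT, and its order turned among short peaks (2.13) and with the mean over peaks (0.59).

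In the TLR4 and NF-kB pathway, which senses LPS, 24 of 31 genes had the lower value in KO, with a median of -0.39 at the 16.3rd percentile. The median was 0.034 with short peaks, the opposite direction and at the 85.9th percentile, whereas with the mean over peaks it was -0.33, at the 0.730th. Examples were Tab1 (3.25 in WT and 2.50 in KO) and Irak2 (2.80 and 1.76), both signal carriers downstream of the receptor. Tab2 differed little (3.26 and 3.13). Tlr4, the receptor itself, was enriched 14.6-fold in WT and 7.99-fold in KO, with the opposite order among short peaks, Traf6, another signal carrier, stood at 3.03 and 1.98 with the same turn, and the feedback inhibitor Tnfaip3 at 3.21 and 2.41, with the opposite order for the mean over peaks. Ikbkb was higher in KO, at 1.51 and 2.29, an order that turned among short peaks.

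The cytokines and mediators induced by LPS were mixed, with 13 of 22 genes lower and 9 higher in KO. Their median of -0.10 lay above that of all genes, at the 79.9th percentile, and was 0.041 (87.6th) with short peaks. Lif stood at 2.47 and 2.11, Acod1, which makes itaconate, at 3.76-fold and 2.01-fold enrichment and Csf1 at 2.90 and 2.57, the last with the opposite order among short peaks. Tnfsf9 stood at 4.58 and 2.75 and Tnf at 1.19 and 0.95, whereas Il1b stood at 0.90 and 1.55. Ptgs2 (0.86 and 1.42) and Nos2 (1.68-fold and 2.07-fold), which make prostaglandin precursors and nitric oxide, were also higher in KO, but Ptgs2 turned at an adjusted p of at most 0.001 and Nos2 among short peaks. The Il1b peaks were at different places, in the 3' UTR in WT and in coding exons in KO. Of the interferon response genes, 21 of 28 had the lower value in KO, with a median of -0.44 at the 6.42nd percentile. It was 0.012 (85.5th) with short peaks and -0.15 (74.6th) with the mean over peaks, both on the other side of the matched lists. Ifnar2, a subunit of the interferon receptor, stood at 3.19 and 2.36 and Cmpk2 at 2.69 and 1.67. Ifit2 stood at 2.85 and 1.99, an order that turned among short peaks. Xaf1 was higher in KO, at 1.34 and 3.29. Among anti-inflammatory and feedback genes, 17 of 19 were lower in KO, with a median of -0.57 at the 6.62nd percentile. It was -0.014 (71.4th) with short peaks, -0.45 (27.3rd) at an adjusted p of at most 0.001 and -0.49 (1.88th) with the mean over peaks. Il10ra, the interleukin-10 receptor, stood at 3.12 and 2.53, Zfp36l2 at 2.41 and 1.33 and Klf4 at 2.74 and 1.42. Klf2 stood at 3.02 and 1.39, an order that turned among short peaks.

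The inflammasome and pyroptosis genes were the group whose KO values lay furthest below matched random lists. Of 11 genes, 10 had the lower value in KO, with a median difference of -0.75 against -0.32 for matched lists, at the 0.565th percentile. The inflammasome sensors Nlrp1b (3.38 in WT and 2.37 in KO), Nlrc4 (2.79 and 2.04), Aim2 (2.69 and 1.63) and Nlrp3 (1.43 and 1.06), the protease Casp1 (1.14 and 0.91) and the ATP receptor P2rx7 (2.21 and 1.32) were among them. The median was -0.60 (7.16th percentile) with peaks at an adjusted p of at most 0.001, -0.15 (17.7th) with short peaks and -0.37 (5.90th) with the mean over peaks, so this position was lost under each.

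Ribosomal protein genes lay at the other end. Of 26 genes, 20 had the higher value in KO, with a median difference of 0.084 (interquartile range 0.017 to 0.14) against -0.17 for matched lists, at the 99.9th percentile when gene span was matched as well. Rps23 stood at 1.01 in WT and 2.19 in KO and Rps19 at 1.44 and 2.01. Rpl18 was lower in KO, at 2.24 and 1.50, with the opposite order among short peaks. Housekeeping genes had a median of 0.070, at the 98.5th percentile, with Gapdh at 1.08 and 2.55, whereas Gusb (1.67 and 1.14, with the opposite order among short peaks), Tbp (1.39 and 1.09) and Ywhaz (1.57 and 0.74) were lower in KO. This median was -0.063, at the 72.7th percentile, with the mean over peaks. The ribosomal median was 0.068, at the 96.2nd percentile, with short peaks. With the mean over peaks the ribosomal median was close to 0 (0.0017), at the 99.9th percentile. Inflammasome, ribosomal and housekeeping genes were the 3 of 18 groups outside the central 95% of matched lists. By chance 0.9 would fall there if the genes of a group varied independently, which was not tested. The percentiles measure the draw of genes and not chance between the genotypes.

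Marker genes of cell types were looked up in both lists. Of 22 microglia identity genes, 16 had peaks in both lists, among them Tmem119 (2.03 in WT and 1.04 in KO), P2ry6 (2.52 and 1.41, an order that turned with the mean over peaks) and Runx1 (2.52 and 1.37, an order that turned among short peaks). Cx3cr1, the fractalkine receptor, stood at 4.59 and 0.63; the WT peak spanned 148930 bases of chromosome 9 and did not overlap the single KO peak. The group's median was -0.12, above that of all genes and at the 66.3rd percentile, and -0.015 (59.9th) with short peaks. Of 20 neuron and neuroblastoma markers, only Tubb3 had a peak, and of 14 astrocyte and oligodendrocyte markers Mbp (4.11 and 1.72, with the opposite order among short peaks) and Cspg4 (2.35, WT only) did.

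The remaining groups lay within the central 95% of matched lists. The cell cycle genes had a median of -0.059 and the RNA decay genes of -0.13, both above the median of all genes; with short peaks they were -0.025 (62.1st) and -0.037 (54.1st). In the first, Cdkn2a stood at 1.75 and 1.65, and Ccnd2 (1.63 and 1.44) and E2f1 (1.48 and 1.36) turned among short peaks. In the second, Upf2 stood at 2.48 and 1.86, Smg6 at 2.37 and 1.60, Smg1 at 2.89 and 1.86 (an order that turned among short peaks) and Dcp1a, an mRNA decapping factor, at 2.85 and 2.06. Unfolded protein and stress genes had a median of -0.30, which was 0.027 (82.3rd) with short peaks and -0.060 (97.4th) with the mean over peaks, with Dnajb9, a chaperone of the endoplasmic reticulum, at 3.05 and 1.82, Eif2ak2 at 3.05 and 2.30, Keap1 at 3.38 and 2.43 and Trib3 at 3.15 and 2.18. Among 7 histone genes it was -0.31, with H1f2 at 3.61 and 3.35, H1f0 at 2.06 and 1.58, H3f3a at 2.04 and 0.56 and H2ax at 3.20 and 2.84. All 6 long noncoding RNAs with peaks in both lists were lower in KO, with a median of -0.84 at the 11.3rd percentile, including Kcnq1ot1 (5.21 and 3.49), Neat1 (3.29 and 2.34), Xist (3.21 and 2.31) and Malat1 (1.73 and 1.36). This median was -0.66 (2.38th) with short peaks and -0.24 (45.9th) with the mean over peaks.

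**Figure D4:**
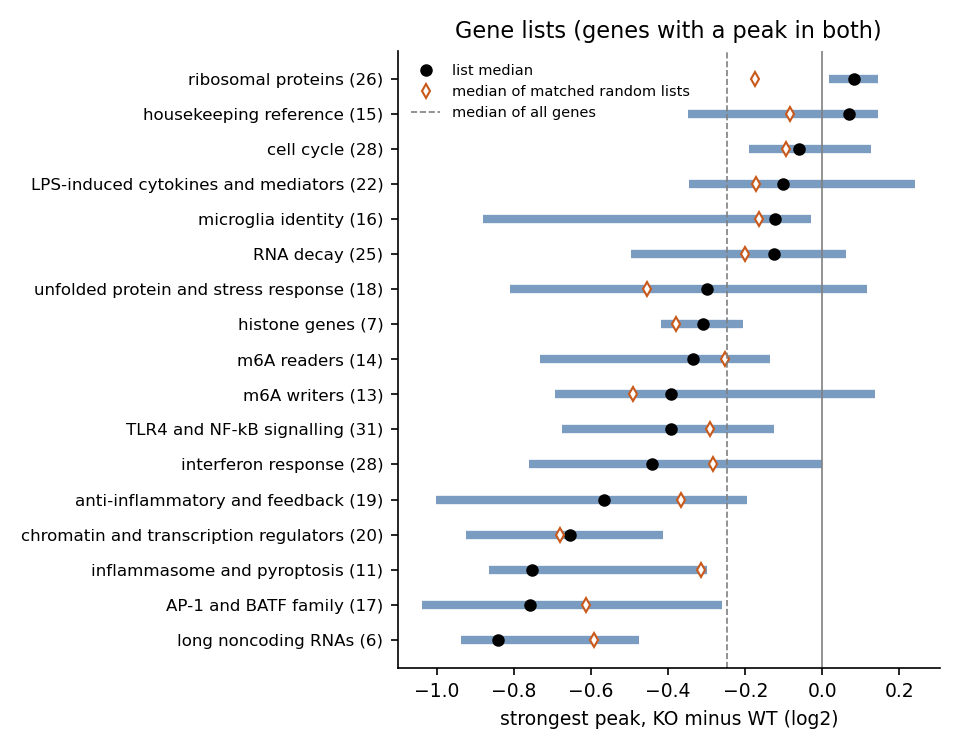
Median KO-minus-WT difference in the log2 of each gene's strongest peak (black points) for the gene groups with at least 5 genes in both lists, with interquartile ranges (bars), the median of matched random lists (open diamonds) and that of all genes (dashed line, -0.25). The number of genes is in brackets. The inflammasome group lies left of its diamond (-0.75 against -0.32), and the ribosomal proteins right of theirs (0.084 against -0.17).

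The strongest single peaks were partly those of genes outside the microglial programme. The WT list was led by Alb, which encodes serum albumin, with a log2 of 8.45 on chromosome 5 from 90462619 to 90476602 (adjusted p = 8.29e-24), then Ttr at 7.99, and included Cyp2e1 at 7.51 and Gc at 7.42. None of these 4 genes had a KO peak, and neither had Gm7292 (7.84), Gm47063 (7.77), Lrfn2 (7.32), Gm18113 (7.02), Gm11595 (6.70) or Apoa1 (6.58). Tenm4 was enriched 145-fold in WT and 32-fold in KO. Input reads per peak are not given here, so the highest folds may rest on few input reads. The adjusted p differed widely at like values: 2.42e-09 for the WT peak of Tenm4 at a log2 of 7.18, and 7.75e-42 for a KO peak of Tm9sf2 at 7.00. The predicted gene Gm14296 (7.73 in WT and 7.26 in KO) and the olfactory receptor gene Olfr1238 (7.37 and 6.80) were near the top of both lists. Among the strongest KO peaks were those of Zfp609 (7.26, against 2.16 in WT, with a lower KO value among short peaks), Olfr49 (7.14, against 3.70), Gm8459 (6.20, against 5.30), Zfp574 (5.76, against 1.37), Gm42031 (5.41, against 1.51) and Kctd1 (5.91, against 5.74, with a lower KO value for the mean over peaks), and Tm9sf2 had an intronic KO peak at 7.00 that had no WT counterpart, although 3 other Tm9sf2 peaks were in the WT list, the strongest at 3.07. The strongest peaks of genes with a KO peak only were those of H2bc12 (5.49), Gm14414 (5.12), Osbpl10 (4.84), Amer3 (4.76) and Gm15516 (4.60), followed by Gm10654 (3.85), A130077B15Rik (3.81), Spag6l (3.78), Selenok-ps8 (3.61) and Fem1al (3.52).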

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

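The tests of a uniform offset and of compression of strong peaks were chosen after their result, or part of it, had been seen; the other tests were set before theirs, those on the ribosome pathway after its excess of higher KO values had been seen without matching. Peaks that the deposited lists tie to no gene entered no gene-level comparison: there were 71 in WT, with a median log2 of 0.88, and 83 in KO, with a median of 0.80.

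Liver transcripts stood out among the strongest WT peaks: 6 noticed there (Alb, Ttr, Cyp2e1, Gc, Apoa1 and Hpx) had no KO peak. Of 53 other hepatocyte genes listed before they were looked up, 6 had a peak; 4 had it in both lists and 2, Apoa2 (log2 of 2.06) and Serpinc1 (1.03), were WT-only, or 33.3% (95% interval 9.68 to 70.0) against 7.44% of all genes. The share of listed genes with a WT-only peak was 2.28 times that in 121 genes of other tissues (2 of 121; two-sided Fisher's exact p = 0.586). With counts this small, RNA of another tissue in the WT libraries and noise at genes with few reads cannot be told apart. No liver sample is among the groups, so no biological explanation was tested.

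The KO list held more but weaker peaks. Depth per library is unknown here, so a difference in depth between the lists could not be tested as a cause. Splitting of wide WT peaks into several KO peaks is argued against as the whole cause, since KO still covered 1.08 times as many merged regions (95% bootstrap interval 1.07 to 1.09). For a uniform offset between the lists, the median difference of identical peaks was compared across 3 equal groups by mean value. It was -0.29 in the strongest and -0.028 in the weakest, a gap of -0.27. Weak pairs enter only if both lists called the peak, which limits how far they can differ, so this gap cannot decide. Among stronger pairs the median was -0.36 (-0.44 to -0.27) at a mean log2 of 1.5 to 2. From 3 upwards it was -0.83 (-1.07 to -0.62), so for those stronger pairs a uniform offset is argued against. A test of whether a lower IP efficiency compressed all strong peaks alike used peaks at the annotated 5' end of genes. Under compression they should shift as much as other identical peaks of like mean value, and otherwise less. They shifted by -0.11 more (-0.17 to -0.05), an interval that leaves out 0 and lies opposite to a smaller shift. The values met neither prediction, so the test cannot decide and compression stays open. Partial loss of METTL3-dependent m6A may also give more but weaker peaks and remains an untested hypothesis, as each genotype has 1 list.

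Ribosomal and respiratory-chain transcripts had higher KO values. Of 125 genes in the KEGG ribosome pathway 75 were higher in KO, and of 104 in oxidative phosphorylation 76, against 3274 of 12323 genes in all. A general upward drift of weak peaks is argued against, since the ribosome pathway's median of 0.047 lay at percentile 100 of 10000 random lists matched on mean value (their median -0.12). Short gene span is argued against in the same way, with percentile 100 when it was matched as well, but the width of the peaks stays open. With peaks of at most 1000 bases the ribosomal protein group was at the 96.2nd percentile, inside the central 95%. Its median stayed positive, at 0.068 against 0.084 with all peaks. Its excess over the median of all genes went from 0.33 to 0.12. With the mean over peaks the group's median was 0.0017, close to 0 though at the 99.9th percentile. The KEGG pathways, and with them the respiratory chain, were not run with short peaks or the mean over peaks. Expression level could not be matched, so depth at abundant transcripts and a relative gain of unmethylated RNA in the KO pull-down both may contribute and stay open.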

How the results depend on the processing

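No paired analysis was possible because the deposited lists carry no replicate columns; leaving out replicates, all input-expression and differential-m6A alternatives, the motif alternatives, positions by midpoint and the filter on expressed genes were not run. The 1000-base limit was applied to genomic span, as exon length is unknown. The alternatives for gene values, identical coordinates, same gene, short-peak overlap and peaks inside the gene were chosen after seeing the data. No coordinates were duplicated in either list, so counting identical rows once changed nothing by construction and is no check. Merging overlapping rows left 36403 WT and 40898 KO peaks, so it had few rows to act on. Only 4 listed hepatocyte genes were among the 12323 genes with a peak in both lists, so leaving out liver genes is a weak check. Keeping peaks inside their gene moved the median difference of all genes from -0.247 to -0.245. Except where a setting is built to remove peaks, the cause of a difference was not tested.

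The larger KO peak count did not hold at 4-fold or more: 4307 WT and 1618 KO peaks, a ratio of 0.376; at an adjusted p of at most 0.001 it was 1.06. The shared percentages of WT and KO peaks were 53.1 and 47.3 at 50% overlap, 78.4 and 76.8 at that adjusted p in both lists, 30.6 and 82.7 at 4-fold in both, 84.4 and 80.8 or 91.5 and 83.7 (KO, then WT) for the stricter peaks of 1 list (adjusted p; 4-fold) against all of the other, 72.6 and 75.7 with equal numbers, 78.2 and 73.9 without strand, and 60.2 and 53.0 with short peaks; 72.5% of KO peaks were shared with the same gene required. Genes in 1 list only numbered 2476 (WT) and 218 (KO) at 4-fold, where 1 gene group passed an adjusted p of 0.05, and 387 and 75 at 4-fold against any peak.

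Median log2 was 0.87 in WT and 0.77 in KO (-0.097) for overlapping peaks, 0.77 and 0.68 (-0.083) for short peaks, and 0.90 and 0.87 (-0.027) for identical coordinates. At 4-fold, 3' UTRs held 57.8% of WT peaks, coding exons 9.54% in WT and 10.01% in KO, 5' UTRs 14.3% in KO, noncoding exons 18.0% and 20.3%, and introns 2.46% and 3.28%.

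Genes with the lower KO value made up 58.2% with short peaks (median -0.054; 412 lower and 148 higher by 1 or more), 77.2% with the mean over peaks (median -0.17; 673 and 49) and, by construction, 50.0% once differences were centred on the median of all genes. Groups with a median between that median and 0 (cytokines, microglia identity, cell cycle, RNA decay) are therefore above it when centred. The housekeeping median was -0.063 with the mean over peaks. Of 85 group values, 77 stayed on their side of the central 95%, a count that is no measure of robustness. Keeping peaks inside their gene and leaving out liver genes removed little, and each gave 17 unchanged values. The inflammasome group moved inside with the stricter adjusted p, with short peaks and with the mean over peaks. The ribosomal group did so with short peaks and the housekeeping group with the mean over peaks. Short peaks turned the medians of writers (0.026), readers (0.039), cytokines (0.041), TLR4 and NF-kB genes (0.034), interferon genes (0.012) and stress genes (0.027), none of which lay outside it with all peaks or with short peaks; with the mean over peaks the TLR4 and NF-kB genes did (0.730th percentile).

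Direction turned with short peaks for 1788 of 9360 genes (19.1%) and 29 of 94 named genes (30.9%), and with the mean over peaks for 1796 of 12323 (14.6%) and 13 of 136 named genes (9.56%). An adjusted p of at most 0.001 turned 1 of 130 named genes, and peaks inside the annotated gene 0 of 134. Many named genes that kept their direction had another difference: 28 with short peaks, where 37 had exactly the same value, and 95 with the mean over peaks, where 28 did. KO minus WT of the genes that turned was, with short peaks, 0.081 for Cbll1, 0.046 for Ccnd2, 0.086 for Csf1, 0.0083 for E2f1, 0.19 for Eif3a, 0.27 for Fto, 0.25 for Gusb, 0.54 for Hnrnpa2b1, 0.21 for Ifit2, 0.0063 for Igf2bp2, -0.15 for Ikbkb, 0.20 for Klf2, 0.34 for Mbp, -0.042 for Mettl3, -0.51 for Mettl5, 2.13 for Myc, -0.12 for Myl2, -0.12 for Nos2, 0.091 for Prrc2a, 0.30 for Rpl18, 0.52 for Runx1, 0.11 for Sbsn, 0.20 for Smg1, 0.094 for Tlr4, 0.32 for Traf6, 0.094 for Ythdf1, 0.071 for Ythdf3, 0.36 for Zcchc4 and -0.39 for Zfp609. With the mean over peaks it was -0.015 for Chd4, -0.42 for Kctd1, -0.049 for Mettl14, -0.13 for Mettl3, -0.046 for Mettl5, 0.59 for Myc, 0.015 for P2ry6, 0.077 for Rbmx, -0.022 for Rbp4, 0.18 for Sfn, 0.38 for Tnfaip3, -0.039 for Trf and -0.059 for Trmt112. At the stricter adjusted p it was -0.11 for Ptgs2.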

Other observations

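Beyond the fixed groups, KEGG pathways named in the deposited lists were compared after seeing the data. Of 204 pathways with at least 30 genes in both lists, 25 lay above the central 95% of matched random lists and 1 below it. By chance 5.1 would fall on each side if the genes of a pathway varied independently, which was not tested. Pathways share genes, so these counts are not independent. The pathways were compared by strongest peaks of any width only. They were not run with short peaks, a stricter adjusted p or the mean over peaks, settings that moved some of the fixed groups. At percentile 100 were the ribosome, oxidative phosphorylation, thermogenesis, retrograde endocannabinoid signalling, non-alcoholic fatty liver disease, and Alzheimer, Huntington and Parkinson disease. Also above were long-term potentiation (99.87th percentile), glutamatergic synapse (99.5th), chemokine signalling (99.25th) and endocytosis (99.3rd). Their medians were negative (-0.0070, -0.054, -0.097 and -0.090) but less so than those of matched lists. Among the higher ones, 28 of 43 proteasome genes had the higher value in KO, with a median difference of 0.048, and the spliceosome pathway had a median of -0.053 against -0.12 for matched lists. Of related pathways, RNA degradation lay above as well, at the 99.4th percentile with 33 of 70 genes higher in KO, whereas ubiquitin mediated proteolysis (22.0th) and mRNA surveillance (52.3rd) lay inside. In oxidative phosphorylation the median was 0.084, with Atp5g1, part of the mitochondrial ATP synthase, at 1.50 in WT and 2.58 in KO and Ndufa1 at 0.93 and 1.12. The only pathway below was AMPK signalling, an energy-sensing kinase pathway, with 69 of 90 genes lower in KO and a median of -0.36 at the 1.41st percentile. Matched on gene span as well, it was at the 3.45th.

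The transcript of Mat2a, S-adenosylmethionine synthetase, is a textbook target of METTL16 and not of METTL3. Its strongest peak, in the 3' UTR, had nearly the same log2 in both lists, 2.75 in WT and 2.71 in KO. Both values were looked up after the other genes had been seen. Mitochondrial transcripts carried 3 WT peaks and 4 KO peaks, and the peak of mt-Nd6 had the same coordinates in both lists, with a log2 of 0.90 and 0.94.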
